A study of Mus musculus with 12 samples.

How the data were processed

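Chromatin immunoprecipitation with an antibody to Nfib was sequenced in the mouse small cell lung cancer lines 16T, KP1 and KP22, with 2 input and 2 pulldown libraries per line and 12 libraries in all. Libraries were grouped by the cell line and sample type in the labels, which also class 16T and KP1 as Nfib high and KP22 as Nfib low. Bowtie2, MACS2, DESeq2 and DESeq and the genome build mm9 are named in the submitters' processing notes, without versions, roles or order. Whether peaks were called per library or on pooled libraries, and at which threshold, is not given in the sources used here. The fragment length, duplicate handling and any scaling before peak calling are likewise not given in the sources used here, and each can change the number and width of peaks.

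The deposited peak lists of KP1 and KP22 hold a start and an end per peak, a blank score column and a strand that is always +. The deposited file for 16T holds 6 file names and 0 intervals and was not used. The deposited table of merged regions has 12 columns from a comparison of high over low, per the file headers. Its base mean is a signal, the mean over libraries of read counts divided by size factors, as the authors' DESeq2 column names give it. Its fold changes and standard errors are on the log2 scale, by the authors. Its test statistics are a score per region, namely Wald statistics by the authors against no change and against an absolute log2 fold change of 0.5 and 1. Its p-value columns hold the authors' p-values and their Benjamini-Hochberg adjusted values. The adjusted values were recomputed from the listed p-values and matched. In the test against 1, the adjusted value is blank for 10362 regions. The lowest base mean of a region with an adjusted value there was 9.56. Of the 34728 merged regions, 180 had a base mean of 0 and were not tested by the authors.

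Which libraries entered the authors' fit was read from the regions of lowest base mean. Single reads gave 6 distinct base means, 4 with a positive and 2 with a negative fold change. All 77 regions with a base mean below 0.65 were whole-number sums of these 6 values, within a tolerance of 2e-07. That is the number of pulldown libraries in the high lines and in the low line, and it leaves no place for pulldowns and inputs together. The inputs alone would give the same split. The headers name the comparison as chip, high against low, so the 6 libraries were taken to be the pulldowns. The size factors this implies run from 0.79 to 1.47, with a geometric mean of 1.00. They were 1.47 and 0.93 on the low side, and 1.05, 1.04, 0.84 and 0.79 on the high side. Fold changes of single reads were as small as 0.46 in size, so the authors' fold changes were shrunken toward 0, and large changes of weak regions are understated.

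Peak widths, chromosomes and windows were computed from the lists in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9. Peaks overlapped when they shared at least 1 base. The overlap was set against 100 sets in which the peaks of each chromosome were moved together around it by a random distance. Shares have exact Clopper-Pearson 95% intervals, and ratios of shares have exact intervals from the binomial split of the peaks. No test between the peak lists was made, since each line has 1 list. Calls in the merged regions are those of the authors at an adjusted p of 0.05. The rule for named regions, fixed before the data were examined, was the 10 largest fold changes in each direction among the regions past that threshold. The same rule named the 10 peaks of highest score in each list, and the 10 widest were described instead because no score was given. That change, the windows of 5 Mb and 1 Mb, the bins of 100 region numbers, the spans of region numbers and the regions of highest base mean were chosen after seeing the data.

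Alternatives fixed before the data were examined were adjusted p thresholds of 0.1 and 0.01, a minimum absolute log2 fold change of 1, a minimum base mean of 20, stricter overlaps of 50% and peaks on the main chromosomes only. Chosen after seeing the data were the authors' tests against 0.5 and 1, a recentring of the fold changes on the median region, and the removal of the regions that span chromosome 4 by rank. The recentred test was tested on simulated data with 34548 regions, the standard errors of the real ones and 200 regions changed. It recovered 0.5% of the changed regions at a log2 change of 1, 21.5% at 2 and 73.5% at 3, with 1, 3 and 5 false calls. The simulated fold changes were not shrunken toward 0 as those of the authors were. These rates therefore do not vouch for the recentred calls in the real data. Placement by rank put the 28281 intervals that the lists gave when joined and the 34728 merged regions in the same order and scaled one rank to the other. The circular shift test used with it was below 0.05 in 5% of 200 simulated tracks without a relation.

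The planned tests on counts per library could not be made, because the table used here gives fold changes and not a value per library. They were quasi-likelihood tests of pulldown against input within each line, of that difference between lines, over the 3 lines and of inputs between lines. Input values were therefore not used here. The merged regions carry no positions, and no mm9 genome or annotation was used here, so genes, distances to transcription start sites and motifs were not analysed. A gene table of the assembly GRCm38.p6 served only to look up the chromosome of Nfib and Mycl, and no position was taken from it.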

Results

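Binding of Nfib (nuclear factor I B, a transcription factor of the nuclear factor I family) was measured by chromatin immunoprecipitation followed by sequencing in 3 mouse small cell lung cancer lines that lack Trp53 and Rb1. The labels class the lines 16T and KP1 as Nfib high and the line KP22 as Nfib low. Each line had 2 input libraries and 2 Nfib pulldown libraries, 12 libraries in all. Peak positions (mm9) were analysed for KP1 and KP22, and fold changes of high over low were taken from the authors' deposited table of 34728 merged regions. The file labelled as the 16T peak list held 0 intervals, so 16T entered only through the merged regions. With 1 low line, the level of Nfib could not be separated from the line itself. Reads per library were not given in the sources used here. The base means in the authors' deposited table summed to 801781 normalised reads per average library. Intervals of shares and ratios below are exact 95% binomial intervals, treat peaks as independent, and cover counting error only.

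The first comparison asked where Nfib peaks lay in a high line and in the low line. KP1 had 24905 peaks and KP22 had 10120, a ratio of 2.46. The KP1 peaks covered 6.82 Mb and the KP22 peaks covered 2.60 Mb. Peaks were of similar median width, with 232 bases in KP1 (quartiles 177 and 323) and 227 bases in KP22 (quartiles 183 and 294). Wide peaks were more frequent in KP1, where 6.77% of peaks had at least 500 bases, against 3.46% in KP22. The narrowest peaks had 150 bases in KP1 (9.51% of the list) and 159 in KP22 (7.84%). Most sites of the low line were also peaks in the high line: 6686 KP22 peaks overlapped a KP1 peak by at least 1 base, which was 66.1% of the list (65.1 to 67.0). In the other direction, 6683 KP1 peaks overlapped a KP22 peak, which was 26.8% (26.3 to 27.4). The lists thus left 18222 peaks called in KP1 alone and 3434 called in KP22 alone. On chromosomes 1 to 19 and X, 6682 of 10106 KP22 peaks overlapped KP1, against a mean of 53.0 and a maximum of 78 over 100 sets of shifted positions. Shared peaks were wider than unshared ones, with medians of 258 against 221 bases in KP1 and 249 against 196 bases in KP22. Each line had 1 list, so the numbers of peaks have no replicate check, and a difference in sequencing depth between the lines would change them.

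The excess of KP1 peaks was spread over all 19 autosomes. The number of KP1 peaks divided by that of KP22 peaks ran from 2.23 on chromosome 19 to 2.80 on chromosome 18. Chromosome X stood apart. It held 253 KP1 peaks, 1.02% of the list (0.895 to 1.15), and 213 KP22 peaks, 2.10% of the list (1.83 to 2.40). The share in KP1 was 0.483 times that in KP22 (0.401 to 0.582), whereas this ratio of shares lay between 0.904 and 1.14 on the autosomes. Chromosome 4, which carries Nfib itself, held similar shares of both lists, with 2147 KP1 peaks (8.62%) and 859 KP22 peaks (8.49%).

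**Figure D1:**
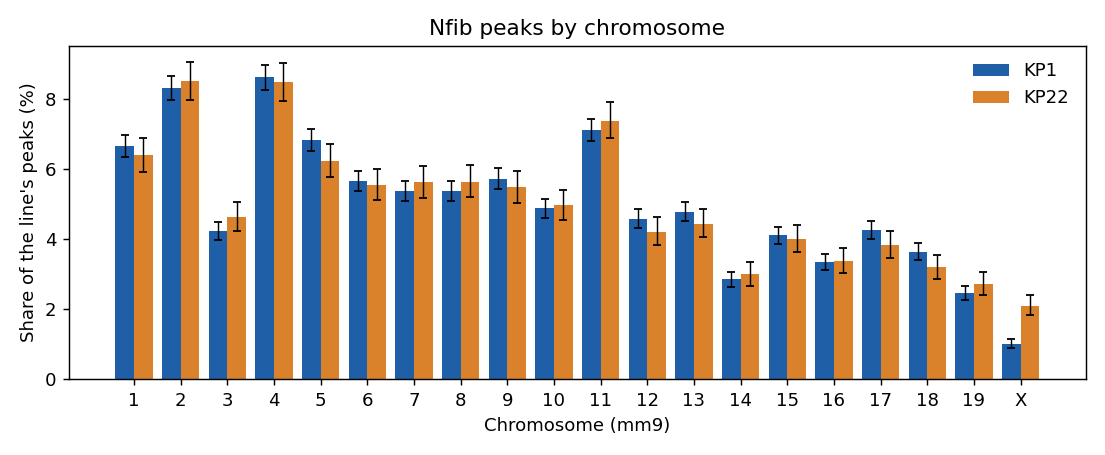
Share of each line's Nfib peaks on each chromosome (x axis, mm9; y axis, percent of the line's peaks), with exact 95% binomial intervals as error bars. The bars of KP1 and KP22 are of similar height on the autosomes, and on chromosome X the KP1 bar stands at 1.02% and the KP22 bar at 2.10%.

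Within chromosome 4, the lines differed by segment. In windows of 5 Mb, the window from 80 to 85 Mb held 125 KP1 peaks and 18 KP22 peaks, a ratio of shares of 2.82 (1.71 to 4.92), the highest among windows with at least 50 peaks. The window from 115 to 120 Mb held 211 and 46 peaks, with a ratio of 1.86 (1.35 to 2.62), and the next one, from 120 to 125 Mb, held 157 and 36, with a ratio of 1.77 (1.23 to 2.62). That window was mixed. Its 1 Mb ratios ran from 1.22 at 121 to 122 Mb to 4.88 at 124 to 125 Mb, with 1.24 (0.770 to 2.05) at 122 to 123 Mb. In that last part the median width was 396.5 bases in KP22 and 215 in KP1. Further along the chromosome the balance turned. The 1 Mb ratio was 0.461 (0.216 to 0.990) at 126 to 127 Mb and 0.492 (0.256 to 0.955) at 127 to 128 Mb. It was back at 1.06 (0.605 to 1.94) at 128 to 129 Mb. The window from 135 to 140 Mb held 232 KP1 and 144 KP22 peaks, a ratio of 0.655 (0.529 to 0.812). The window from 145 to 150 Mb held 53 KP1 and 60 KP22 peaks, a ratio of 0.359 (0.243 to 0.528), the lowest among windows with at least 50 peaks. On other chromosomes, the ratio was highest on chromosome 1 from 55 to 60 Mb, where 52 KP1 peaks stood against 8 (2.64, 1.25 to 6.44), and on chromosome 17 from 65 to 70 Mb, where 81 stood against 13 (2.53, 1.40 to 4.96). The windows were chosen after the lists were seen, and the intervals are not adjusted for the number of windows.

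**Figure D2:**
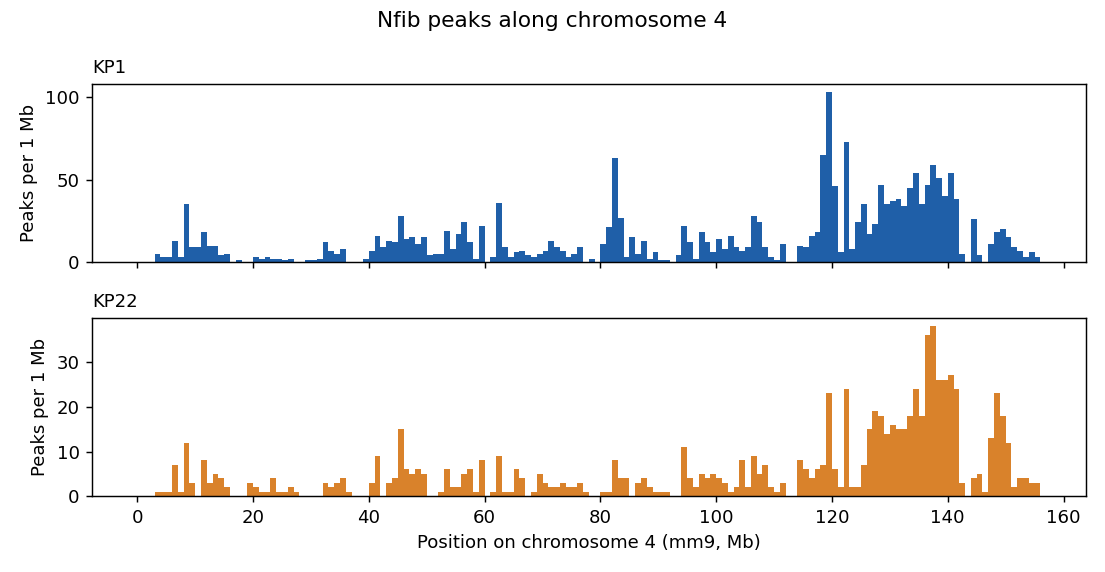
Nfib peaks per 1 Mb along chromosome 4 (x axis, mm9 position in Mb; y axis, number of peaks) in KP1 (top) and KP22 (bottom), on separate scales. KP1 reaches 103 peaks from 119 to 120 Mb and 63 peaks from 82 to 83 Mb, where KP22 has 23 and 8, and KP22 is highest from 137 to 138 Mb with 38 peaks.

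Of the 10 densest 1 Mb windows, 7 in KP1 and 6 in KP22 lay on chromosome 4. Ties at the last places were broken by order in the data, so both counts could differ. KP1 also had 51 peaks at 138 to 139 Mb of chromosome 4, equal to the last one counted. KP22 also had 24 at 134 to 135 Mb and at 141 to 142 Mb, equal to its last ones. In KP1, 103 peaks fell between 119 and 120 Mb, 73 between 122 and 123 Mb and 65 between 118 and 119 Mb of chromosome 4, against a median of 8 per window with peaks. In KP22, 38 peaks fell between 137 and 138 Mb and 36 between 136 and 137 Mb of chromosome 4, followed by 30 on chromosome 11 between 117 and 118 Mb, against a median of 4. Wide peaks were also more frequent on chromosome 4. Of 1687 KP1 peaks of at least 500 bases, 235 lay on chromosome 4, which was 13.9% (12.3 to 15.7) against 8.62% of all KP1 peaks. Of 350 such KP22 peaks, 75 lay on chromosome 4, which was 21.4% (17.2 to 26.1) against 8.49% of all.

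The widest KP1 peak lay on chromosome 17 from 39979954 to 39985758 and spanned 5805 bases. It held a pair of KP22 peaks, from 39980047 to 39981108 and from 39983223 to 39984323. The next in KP1 lay on chromosome 4 from 122672620 to 122674757 (2138 bases) and on chromosome 9 from 3001648 to 3003765 (2118 bases). Of the 10 widest KP1 peaks, 5 lay on chromosome 9 and 3 on chromosome 4. The 5 on chromosome 9 all lay between 3001648 and 3033009. Repeats and mappability were not analysed here, so the width of a peak alone does not show Nfib binding. The widest KP22 peak lay on chromosome 13 from 71157136 to 71159678 (2543 bases). It was followed by peaks on chromosome 4 from 122727467 to 122728783 and from 127031090 to 127032406, each of 1317 bases. Of the 10 widest KP22 peaks, 6 lay on chromosome 4. These peaks were described by width because the score column of both lists was blank. Genes at these positions were not analysed here, since the gene table at hand is of another genome build.

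The second comparison asked which Nfib regions differed between the high lines and the low line. In the authors' deposited table, 12973 of the 34548 merged regions with reads (37.6%) passed an adjusted p of 0.05 by the authors' DESeq2 Wald test. Of these, 11751 were higher in the high lines and 1222 were lower, so that 90.6% (90.1 to 91.1) were higher. KP22 had 10120 peaks against 34728 merged regions, so most regions hold no KP22 peak if they were joined from the lines' lists. Such a choice of regions would favour higher calls. The fold changes in the authors' deposited table lay above 0 for 26096 regions (75.5%), with a median log2 fold change of 1.06 (quartiles 0.02 and 2.09). With the median of 1.06 subtracted from every log2 fold change in the authors' deposited table, 4199 regions were higher and 5692 lower, so that 42.5% of the calls were higher. Such a centring balances all regions about the new centre by construction, whatever the source of the shift. It does not fix the split of the calls, which also depends on their sizes and standard errors. The fold changes were shrunken toward 0 and not toward the new centre, which may distort this split. The authors' deposited table also tests against a minimum change, and at an absolute log2 fold change above 1 it called 3751 regions higher and 161 lower. The labels do not say whether replicates came from separate cultures, so these p-values may measure a technical spread. Libraries served as replicates and KP22 was the only low line, so spread among low lines is not in these p-values. They therefore do not test an effect of the level of Nfib apart from the line. A region called higher may also rest on a single high line, which cannot be seen without values per library.

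**Figure D3:**
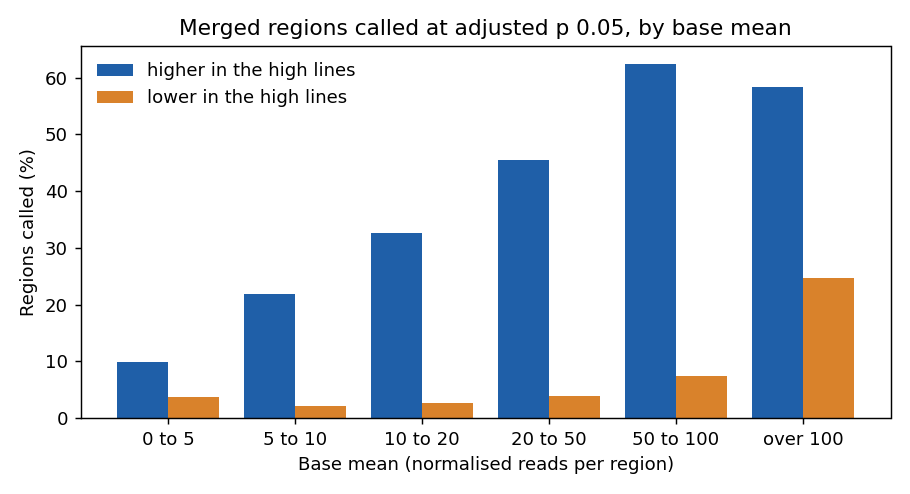
Percent of merged regions in the authors' deposited table called at an adjusted p of 0.05 (y axis), by base mean in normalised reads (x axis), higher (blue) or lower (orange) in the high lines. The share called in either direction rises from 13.6% of regions with a base mean of up to 5 to 83.1% of those over 100.

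Regions with more reads were called more often. The median region had a base mean of 13.9 normalised reads (quartiles 8.73 and 24.4) and a standard error of 0.69 on the log2 scale in the authors' deposited table. Of the regions with a base mean of up to 5, 13.6% were called in the authors' deposited table, against 83.1% of the regions over 100. Among the latter, 393 were called higher and 167 lower in the authors' deposited table.

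The region with the largest rise in the authors' deposited table was nfib_peak_22168, with a log2 fold change of 8.13 ± 0.58 (SE by the authors), a base mean of 490.5 and an adjusted p of 4.52e-42. It was followed in the authors' deposited table by nfib_peak_22167 at 6.91 ± 0.65, nfib_peak_22912 at 6.63 ± 0.50 and nfib_peak_22736 at 6.51 ± 0.49. The remaining 6 of the 10 largest rises ran from 6.28 to 6.44 in the authors' deposited table, among them nfib_peak_22836 at 6.28 ± 0.32 with a base mean of 666.4. The largest fall in the authors' deposited table was that of nfib_peak_23110, at -6.71 ± 0.39 with an adjusted p of 5.89e-63. Next in the authors' deposited table came nfib_peak_22992 at -6.66 ± 0.23, nfib_peak_23105 at -6.60 ± 0.48 and nfib_peak_23137 at -6.53 ± 0.25. The remaining 6 of the 10 largest falls ran from -6.50 to -6.20 in the authors' deposited table. Each of these 20 regions changed by far more than the median shift of 1.06.

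Rows of the authors' deposited table carry a number and no position, and the named falls lay closer together in that numbering than the named rises. All 10 of the largest falls in the authors' deposited table had numbers between 22990 and 23137, a span of 147. The 10 largest rises in the authors' deposited table had numbers between 19848 and 31596, a span of 11748. Of these rises in the authors' deposited table, 6 had numbers between 22101 and 23200, the range of the bins with the highest median base means, and 4 lay outside. The highest base mean in the authors' deposited table belonged to nfib_peak_14032, at 9933 normalised reads with a log2 fold change of 1.37 ± 0.14. The second, nfib_peak_22967, had a base mean of 6691 and a log2 fold change of -2.27 ± 0.15 in the authors' deposited table. The third, nfib_peak_17997, had a base mean of 3465 and a log2 fold change of -0.05 ± 0.18, with an adjusted p of 0.843 in the authors' deposited table.

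**Figure D4:**
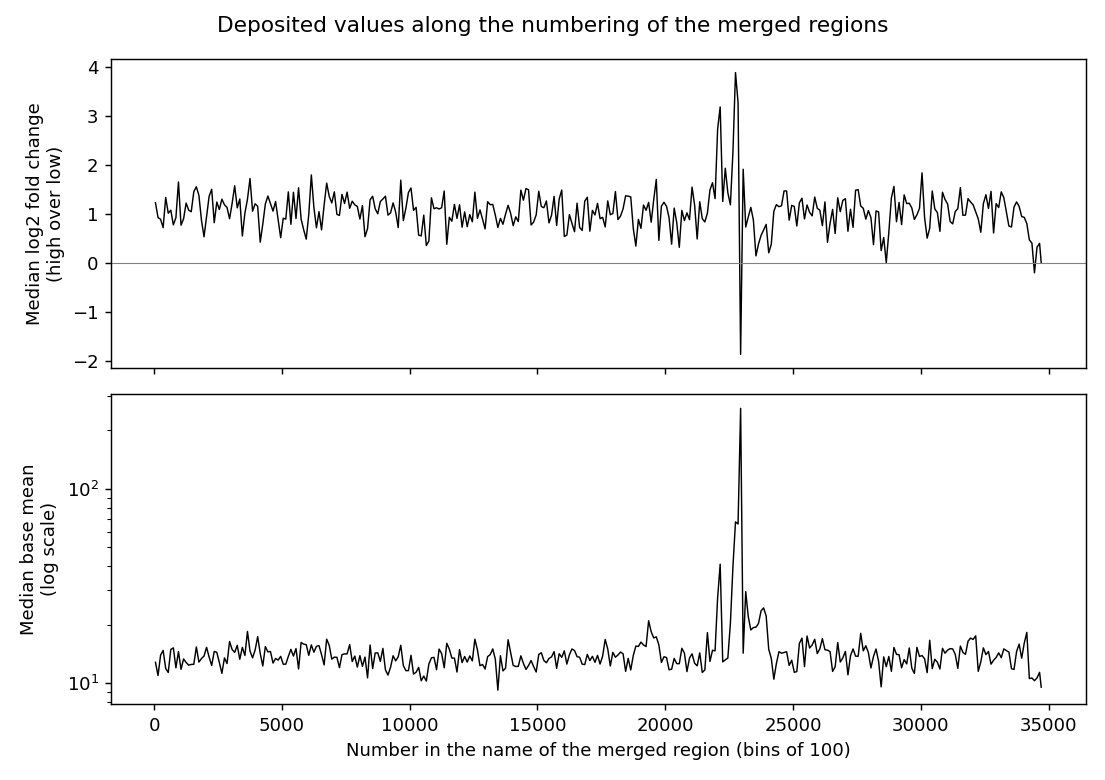
Median log2 fold change of high over low (top) and median base mean in normalised reads on a log scale (bottom) in the authors' deposited table, in bins of 100 consecutively numbered merged regions (x axis, number in the region's name). The base mean exceeds 2 times the overall median in 6 of 348 bins, all between numbers 22101 and 23200, and the median log2 fold change there runs from -1.86 to 3.88.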

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

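The authors' tests against a minimum change, the recentring and the removal of regions by rank were chosen after seeing the data. Calls higher in the high lines stayed in the majority in all alternatives except the recentring. The 12973 calls became 6172 at a base mean of at least 20, 7364 against a log2 change of 0.5 and 3912 against 1, each by construction, since fewer regions can pass. Under the other alternatives they ran from 8693 at an adjusted p of 0.01 to 15734 at 0.1. The percentage of calls that were higher, 90.6%, was 88.7% at an adjusted p of 0.1, 92.6% at 0.01, 91.2% with an absolute log2 fold change of at least 1, 89.5% at a base mean of at least 20, 94.1% in the test against 0.5 and 95.9% in the test against 1. It was 91.5% without the regions that span chromosome 4 by rank. Recentred on the median region, 9891 regions passed and 42.5% of them were higher. Centring balances all regions about the median by construction but does not fix the split of the calls. This value does not show where the shift comes from, and the shrinkage of the fold changes toward 0 may distort it. A reciprocal overlap of at least 50% lowered the shared part of KP1 to 22.2% and that of KP22 to 54.6%, since it asks for more overlap, and 50% of the shorter peak gave 26.5% and 65.4%. The lists held 24869 and 10106 peaks on the main chromosomes.

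No paired analysis was possible because the table used here holds no value per library. For the same reason, leaving out each replicate, other normalizations, filters and tests on counts were not run. A stricter selection of peaks by score was not run because the scores are blank, and gene lists, distances to transcription start sites and motifs were not run because regions could not be tied to an mm9 annotation. The precision limits the calls: for regions with a base mean of up to 5 the median standard error was 1.07 on the log2 scale, so a log2 change of 1 is smaller than its error there.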

Other observations

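All tests in this part were chosen after the results were seen. The runs of numbers with high base means in the authors' deposited table form neighbouring blocks that go opposite ways. In the authors' deposited table, all 100 regions numbered 22801 to 22900 were called higher and 98 of the 100 numbered 22701 to 22800, with median log2 fold changes of 3.27 and 3.88. In the next bin of the authors' deposited table, 22901 to 23000, 72 of 99 regions were called lower, with a median of -1.86 and a median base mean of 259 normalised reads. Among 1000 permutations of the base means over the regions, the highest median of any bin was 25.5.

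The first pattern is this set of runs: if region numbers follow genome position in the order of the peak lists, the local balance of KP1 and KP22 peaks by rank should track the local fold change by number. Outside chromosome 4 the correlation across bins was r = 0.488, and no circular shift exceeded 0.272, which is consistent with that order (neighbouring bins are not independent replicates). By this rank the runs may lie on chromosome 4: 119 to 120 Mb had a median log2 fold change of 3.96 over 126 regions, 82 to 83 Mb had 3.60 over 78, 122 to 123 Mb had -1.95 over 94 and 126 to 127 Mb had -4.50 over 29, all from the authors' deposited table; of the 6 windows there of 1 Mb, with at least 20 intervals, that had a negative value, the KP1 over KP22 ratio of peak shares was below 1 in 4 (0.318 to 0.790, with 0.461 at 126 to 127 Mb) and above 1 in 2, at 1.24 at 122 to 123 Mb and 2.64 at 144 to 145 Mb, so the placement of single windows is uncertain. Copy number gain of parts of chromosome 4, in 1 or more lines, cannot be told apart from clustered binding. With a gain, weaker regions should shift with their run. The median over the 6 runs of the share on the run's side was 69% (42% to 100%), between the bounds of 60% and 75% set for the test. No single run lay between these bounds, so the median hides a split. The share was 78% in 22101 to 22200 and 100% in 22701 to 22800 and in 22801 to 22900. It was 56% in 22601 to 22700, 60% in 22901 to 23000 and 42% in 23101 to 23200. Each run includes its weaker regions, so the share is not independent of the run's side. In another form of the test, the share called one way exceeded that of every other bin in 3 of 6 runs. The highest other, 77% in 22001 to 22100, borders a run. In 5 of 6 it exceeded that of every bin not next to a run, 53% at most. The share called rises with base mean, by which the runs were picked, so a higher share there does not separate copy number from binding. A form on the lowest base means of each run decided nothing, since the runs were picked by base mean, the fixed bins cut across the edges of runs, and the inputs, which would show copy number, were not used here.

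The second pattern is that most called regions were higher in the high lines. A scaling offset between the libraries should shift weak and strong regions alike, before any shrinkage of the fold changes. The lowest median log2 fold change over the 6 ranges of base mean in the authors' deposited table was 0.905, against 1.06 over all regions. The shift was thus positive in all 6 ranges. The authors' fold changes were shrunken, which understates large changes of weak regions, so the medians cannot show whether the shift was equal. An offset therefore stays open and is not decided by these values. Wider binding in the high lines, which the design names, would give the same shift and stays open, as untested. The lists held 2.46 times as many peaks in KP1 as in KP22. KP22 had 10120 peaks against 34728 merged regions. If the regions were joined from the lines' lists, most of them hold no KP22 peak and may lean toward higher calls. How much of the excess this made cannot be told apart here, because nothing used here links a merged region to a list.

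The third pattern is the low share of KP1 peaks on chromosome X. The merged regions placed there by rank had a median log2 fold change of 0.33 in the authors' deposited table, against 1.07 elsewhere, a difference of -0.744. Of these regions, 85 were called higher and 46 lower in the authors' deposited table. KP1 and KP22 enter both the peak lists and the fold change, so the lower value there restates the pattern, and a difference of the whole chromosome between the lines, for example in its copy number, cannot be told apart from a difference in Nfib binding on it.

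The merged region of highest base mean, nfib_peak_14032, has a number close to 14028, the place by rank of the widest KP1 peak, on chromosome 17. The merged table holds 6447 more regions than the 28281 intervals of the joined lists. Nfib and Mycl, a Myc family gene, are both on chromosome 4 in the gene table, and their positions were not compared with the peaks.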
